A study of Mus musculus with 3 samples.

How the data were processed

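Gene expression was measured on 3 single-colour Affymetrix arrays, each hybridised with biotin-labelled cDNA amplified from the total RNA of mouse bone marrow stromal cells sorted by flow cytometry. Per the labels' protocols, sorted cells were lysed at once, RNA was purified on small-scale columns, and cDNA was made with a NuGEN whole-transcript amplification kit for picogram to nanogram inputs. Of the arrays, 2 hold CXCL12-abundant reticular (CAR) cells of 2 Cxcl12-GFP knock-in mice, and 1 holds cells combined from 3 Prx1-Cre; Rosa26-Ai9; Cxcl12-GFP mice and gated as PDGFRα+ Sca-1+ CD45− lineage−, called PaS here. Samples were grouped by the cell type in their labels. The CAR arrays are labelled as separate replicates of 2 mice; the PaS group is 1 pooled array without replicates.

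The values deposited by the authors are signal intensities on a linear scale, 1 per probe set. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, a procedure of background correction, quantile normalization of probes and summary per probe set; versions are not given in the sources used here, nor is a genome build. The deposited values were never negative, ran from 1.23 to 12259 on CAR array 1, and had medians of 11.9, 11.3 and 12.8 on CAR array 1, CAR array 2 and the PaS array. Log2 of the intensity was taken with no pseudocount, which the design had foreseen for values that are not on a log scale. No detection calls were used here, so a low value cannot be told from background, and folds against such values are uncertain in size. The low end of the values also differed between arrays: the 5th percentile over genes was 1.87 and 1.69 log2 units on the CAR arrays and 2.40 on the PaS array. A dim gene can therefore appear lower in CAR cells without a difference in expression. The summarised distributions still differed between arrays: the interquartile range over genes was 1.96 and 2.28 log2 units on the CAR arrays and 1.35 on the PaS array. The cause of this difference was not tested.

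Of 35556 probe sets, 21789 carried 1 gene symbol in the platform annotation used here, 1621 carried several and were not named or tested, and 12146 were unnamed here. Gene identifiers of 21698 probe sets matched the current gene table, from which symbols were taken; no coordinates were used because no build is named for the array. A gene with several probe sets (999 genes) was represented by the probe set with the highest mean over the 3 arrays, which left 19938 genes.

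The comparison of CAR with PaS was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default moderation, no covariate), two-sided, with Benjamini-Hochberg adjustment over all 19938 genes and a threshold of 0.05. With 2 arrays against 1 the fit has 1 residual degree of freedom; moderation added 4.20 prior degrees of freedom around a prior SD of 0.25 log2 units. The spread therefore comes from the CAR arrays alone, and the PaS array is assumed to vary like them. Errors given as SE are limma's moderated standard errors, and SDs are over the 2 CAR arrays. The number of arrays limits the precision. A count by size, with no test, took genes at least 2-fold (1 log2 unit) apart in both CAR arrays. On simulated arrays of the same design and 19938 genes, with 50 genes changed at each size, the fit called 0% of genes changed by 1 log2 unit, 8% at 2 units, 72% at 3 units and 100% at 4 units, with 6 false calls among 96. Only 200 genes were changed there, whereas 15.0% of all genes were called in the data. The adjustment is stricter when fewer genes differ, so these rates do not carry over to the data, where the smallest called difference was 1.18 log2 units.

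The 29 gene lists, the rule for named genes, the tests and the alternative settings were fixed before the data were examined. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists, and each list's median difference was set against 10000 random lists matched on mean expression in 20 bins. Camera was also run with an estimated correlation, which leaves it 1 degree of freedom. Of 835 list entries, 754 were measured by a probe set with 1 symbol. Lists overlap: 14 of the 26 genes of the CAR list and 9 of the 30 of the Sca-1+ list also stand in another list. The text names 10 genes of the sorts and the niche, the 12 genes with the largest difference in each direction among those past the threshold, with both CAR arrays on one side of the PaS array and the higher group mean at or above the median level (predicted and clone-named genes, microRNAs, small nucleolar RNAs, olfactory and vomeronasal receptors left out), and up to 4 members of each list with the largest difference. Named outside this rule are S100a8, S100a9, Lyz2, H2-Eb1, Acan, Cytl1, Col2a1, Sox9 and Col9a1. Ly6a, which encodes Sca-1, had no probe set of its own in the annotation and is not analysed here.

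Alternatives were centring each array on its median, quantile normalization of the 3 arrays, a filter on dim genes, the mean of all probe sets of a gene, eBayes with a trend or a robust prior, a test against 1 log2 unit (treat), a looser and a larger threshold, leaving out each CAR array, and camera on ranks. Left out of all tests were the unnamed probe sets, which include the array's control probe sets.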

Results

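The study asked which stromal cells of the bone marrow supply the chemokine CXCL12 to hematopoietic stem cells, and the arrays set 2 stromal populations side by side at baseline. CAR cells are reticular cells with a high level of Cxcl12, sorted from tibia, femur and pelvis of knock-in mice that carry GFP at the Cxcl12 locus. PaS cells are mesenchymal progenitors defined by PDGFRα and Sca-1 on the surface and by the absence of CD45 and lineage antigens; here they came from mice with the Prx1-Cre limb mesenchyme driver, a Rosa26 reporter and the Cxcl12-GFP allele. There were 2 CAR arrays and 1 PaS array from a pool of 3 mice. Genotype and cell type therefore differ together, and the PaS side has no replicate error.

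The genes that define the sorts were read first. Cxcl12 stood at a log2 intensity of 11.03 ± 0.12 (SD, n = 2) in CAR cells and at 7.76 on the array labelled PaS, a 9.63-fold difference (log2 difference 3.27 ± 0.29, SE; limma adjusted p = 0.0114). Pdgfra, the receptor used to gate PaS cells, was 10.7-fold higher in CAR cells (7.75 ± 0.32 against 4.33; adjusted p = 0.0119), and its PaS value lay between the median, 3.77, and the upper quartile, 4.52, of all genes on that array. Prrx1, the gene whose promoter drives the Prx1-Cre allele, was 6.35-fold higher in CAR cells (log2 difference 2.67 ± 0.30, adjusted p = 0.0143). Ptprc, which encodes CD45, was 9.28-fold lower in CAR cells (5.06 ± 0.07 against 8.27; adjusted p = 0.0114), although CD45+ cells were gated out of the PaS sort. The levels of Pdgfra and Ptprc thus run against the label of the PaS array, and every direction below is between the CAR arrays and the array labelled PaS. Dilution of that sample by RNA of blood cells, which is weighed below, would enlarge the folds of stromal genes toward CAR cells. Those folds therefore cannot be read as differences between pure cell types.

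**Figure D1:**
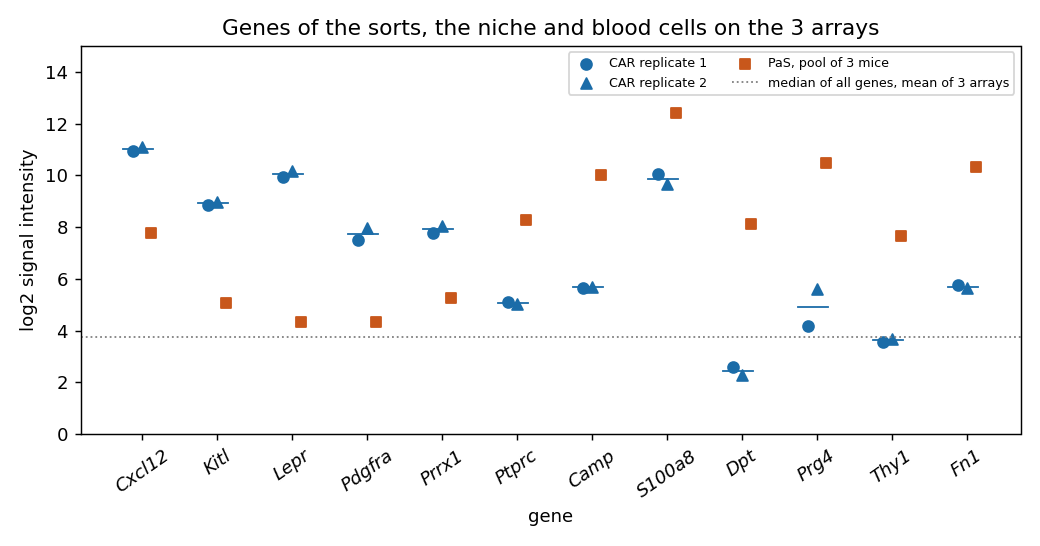
Log2 signal intensity of 12 genes on the 3 arrays: blue circles and triangles are CAR replicates 1 and 2 with a line at their mean, orange squares the array labelled PaS, and the dotted line the median of all genes averaged over the 3 arrays. The CAR replicates lie close together for most genes, Cxcl12, Kitl, Lepr, Pdgfra and Prrx1 lie higher in CAR cells, and Ptprc, Camp, S100a8, Dpt, Prg4, Thy1 and Fn1 lie higher on the array labelled PaS.

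Over 19938 genes, 1706 were higher in CAR cells and 1281 lower (limma, adjusted p under 0.05), and 2178 genes were at least 2-fold higher and 1778 at least 2-fold lower in both CAR arrays. Of the 1281 lower calls, 876 were genes with a mean over the 3 arrays below the median level. Such dim genes can appear lower in CAR cells without a difference in expression, because the low end of values differed between arrays. The CAR arrays correlated at r = 0.963 across genes with each other and at 0.764 each with the array labelled PaS; genes are not independent replicates. The SD of the log2 differences was 0.45 between the CAR arrays, against 0.97 and 1.06 between each of them and the array labelled PaS. With CAR array 1 or CAR array 2 taken as the single array instead, 173 and 334 genes were at least 2-fold apart from both other arrays, against 3956 for the array labelled PaS; with 3 arrays, a given array is the one farthest apart in 33.3% of cases by chance. The array labelled PaS had a narrower spread of values. Quantile normalization, which equalises the spread, gave 1992 genes at least 2-fold higher and 1601 lower in both CAR arrays. Centring each array on its median, which leaves the spread unchanged, gave 2544 higher and 1338 lower. The balance of limma calls depended on the setting: 2062 were higher in CAR cells and 510 lower among genes at or above the median level, 2824 and 2533 after quantile normalization, and 1613 and 1751, the opposite balance, with an intensity trend in the variance.

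The 12 largest differences toward CAR cells ran from 40.6-fold to 159-fold. On the array labelled PaS all of these genes but Lepr, Igfbp4, Esm1 and Pappa lay below the median of all genes, 3.77, so exact folds and their order are uncertain. Gdpd2, a glycerophosphodiester phosphodiesterase, was 159-fold higher (log2 difference 7.31 ± 0.30, SE), Fgf7, a growth factor for epithelial cells, 83.9-fold and Lepr, the leptin receptor, 52.1-fold. The insulin-like growth factor binding proteins Igfbp4 and Igfbp3 were 49.4-fold and 49.3-fold higher, and Pappa, a protease that cleaves Igfbp4, was 44.7-fold higher. Esm1 (48.8-fold), a secreted proteoglycan, Kng1 (log2 difference 5.49), the kinin precursor, Gpx8 (44.2-fold), a peroxidase of the endoplasmic reticulum, Mmp13 (43.4-fold), a collagenase, Vegfc (40.6-fold), a lymphatic growth factor, and Lpp (40.6-fold), a focal adhesion protein, completed the 12. The value of Lpp rests on its brightest probe set, and the mean of its 3 probe sets gave a log2 difference of 3.24 instead of 5.34. The CAR arrays were unequal for Igfbp3, at 8.68 and 9.88 against 3.65. Each had an adjusted p between 0.0081 and 0.0116 in limma's test.

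In the other direction Dpt, a dermal matrix protein of fibroblasts, was 50.7-fold lower in CAR cells (2.44 ± 0.23 against 8.10), and Prg4, the joint lubricant of synovial and superficial cartilage cells, was 47.5-fold lower (4.89 ± 1.02 against 10.46). Fn1, fibronectin, was 24.5-fold lower, Clec3a, a cartilage lectin, 23.4-fold, and S100a4, a calcium-binding protein of fibroblasts and myeloid cells, 15.8-fold. Thy1, present on fibroblasts and on T cells, was 16.6-fold lower, and Slc38a1, an amino acid transporter, 15.9-fold, or 2.24 instead of 3.99 log2 units with the mean of its 2 probe sets. Genes of blood cells made up part of the rest: the neutrophil granule gene Camp was 20.1-fold lower, the neutrophil surface gene Ly6g 16.6-fold and the lymphoid recombinase gene Rag1 15.5-fold. Of the whey acidic protein family, Wfdc21 was 15.6-fold lower and Wfdc17 24.2-fold, the latter with unequal CAR arrays at 2.52 and 5.04 against 8.38. Adjusted p lay between 0.0081 and 0.0428 over the 12 in limma's test. The CAR means of Dpt, Clec3a, Ly6g, Thy1, Slc38a1 and Rag1 lay below the medians of all genes on the CAR arrays, 3.74 and 3.75. Exact folds and their order are therefore uncertain here too.

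**Figure D2:**
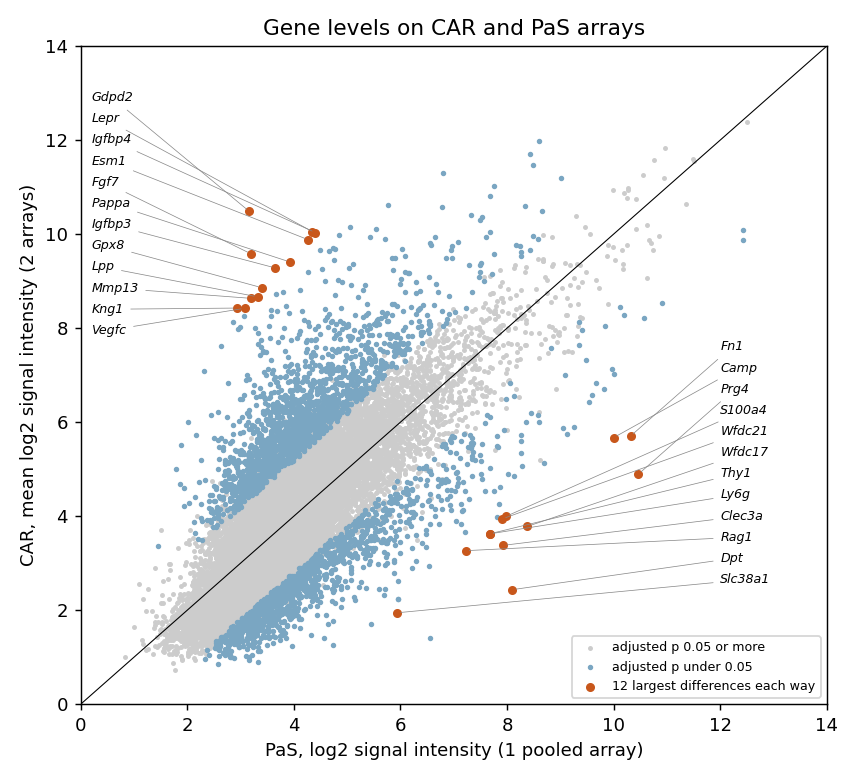
Mean log2 signal intensity of the 2 CAR arrays (vertical axis) against the log2 intensity of the array labelled PaS (horizontal axis), 1 point per gene, with the line of equality. Blue points passed an adjusted p of 0.05 in limma, grey points did not, and orange points are the 12 named genes with the largest difference in each direction, from Gdpd2 at 159-fold higher to Dpt at 50.7-fold lower in CAR cells.

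Genes of the hematopoietic niche were higher in CAR cells than on the array labelled PaS. Of 20 measured niche factors, 10 rose and 0 fell in the test over all genes (13 and 2 adjusted over the list alone), with a median log2 difference of 1.49. Kitl, the ligand of the stem cell receptor Kit, was 14.3-fold higher (log2 difference 3.84 ± 0.28, SE; adjusted p = 0.00914). Angpt1, the ligand of Tie2, was 20.4-fold higher, Vcam1, an adhesion molecule for blood cells, 7.06-fold, and Il7, a lymphoid growth factor, 6.56-fold. Csf1 and Cdh2 were 18.9-fold and 21.3-fold higher. Markers of CAR and leptin receptor-positive stroma rose almost throughout, with 25 of 26 measured genes past the test both over all genes and adjusted over the list alone, a median difference of 3.42, and Lepr, Igfbp4, Esm1 and Chrdl1 (36.0-fold, a BMP antagonist) in front. Camera gave adjusted p = 8.47e-07 for niche factors and 5.2e-21 for CAR markers (adjusted p = 0.600 for each with an estimated correlation), and both medians lay above the middle 95% of matched random lists.

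Markers of Sca-1+ progenitors and fibroblasts were mostly lower in CAR cells. Of 27 measured genes, 16 fell and 2 rose (18 and 3 adjusted over the list alone), with a median of −1.36. Dpt, Thy1 and S100a4 fell by 5.66, 4.05 and 3.98 on the log2 scale, and Pdgfra was among the 2 that rose. For this list camera gave adjusted p = 7.77e-06 (adjusted p = 0.600 with an estimated correlation). Thy1, S100a4 and other members of the list are also made by blood cells, whose markers moved the same way: the median of the general blood cell list was −1.90.

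Lineage genes differed in direction. For the osteoblast lineage 9 of 25 measured genes rose and 1 fell (11 and 2 adjusted over the list alone): Mmp13 led, Cdh11, a mesenchymal cadherin, was 23.7-fold higher, Ibsp, bone sialoprotein, 22.7-fold, and Dlx5, an osteoblast transcription factor, 8.60-fold. For the adipocyte lineage 7 of 27 rose and 2 fell (11 and 2 adjusted over the list alone). Lpl, lipoprotein lipase, was 29.1-fold higher, Adipoq, adiponectin, 25.9-fold, Agt, angiotensinogen, 9.79-fold, and Apoe 9.56-fold. For the chondrocyte lineage 0 of 27 rose and 4 fell (0 and 5 adjusted over the list alone); these were Prg4, Chad (11.7-fold lower), Comp (4.35-fold lower) and Fmod (3.01-fold lower), the last 3 encoding matrix proteins of cartilage and tendon. Camera gave adjusted p = 0.00582 for the osteoblast, 0.0477 for the adipocyte and 0.0149 for the chondrocyte list (adjusted p = 0.600 for each with an estimated correlation). The adipocyte list had a median of 0.06 (0.31 and 0.18 with CAR array 1 or 2 alone) and a mean of 0.68, and its call was also lost with quantile normalization (adjusted p = 0.212), genes at or above the median level (0.226), the mean of all probe sets of a gene (0.0520) and camera on ranks (0.0994); its median lay within the middle 95% of matched random lists. Chad differed between the CAR arrays, at 2.99 and 4.33 against 7.21. Without CAR array 2 the median of the osteoblast list was 0.35 instead of 0.82, and that of the chondrocyte list −0.27 instead of −0.51.

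Signalling and matrix genes were mixed but leaned to CAR cells. In the BMP, TGF-beta and Wnt list 22 of 53 measured genes rose and 2 fell (26 and 3 adjusted over the list alone), led by Chrdl1 and by the ligands Bmp6 (33.1-fold), Bmp5 (16.1-fold) and Bmp4 (15.3-fold). In the matrix list 18 of 50 rose and 7 fell (24 and 13 adjusted over the list alone), with Fbln5, an elastic fibre protein, higher 34.7-fold, Tnc, tenascin C, by 4.25 log2 units and Lamc1, a laminin chain, 18.9-fold, and Fn1 lower. Camera gave adjusted p = 3.93e-08 and 0.0022 (adjusted p = 0.600 for each with an estimated correlation); the matrix call was lost after quantile normalization (adjusted p = 0.0929) and among genes at or above the median level (0.0924), and the list's median of 0.58 lay within the middle 95% of matched random lists. Of 32 chemokines and cytokines 8 rose and 3 fell (10 and 3 adjusted over the list alone), camera adjusted p = 0.193, with Csf1, Cxcl9 (log2 difference 3.46) and Il34 (9.16-fold) higher and the neutrophil chemokine Cxcl2 8.27-fold lower.

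Markers of blood cells were lower in CAR cells, that is, higher on the array labelled PaS. Of 21 measured general blood cell genes 13 fell and 0 rose (17 and 0 adjusted over the list alone), among them Cd53 (11.9-fold lower), Ptprc, Itgb2, the leukocyte integrin chain (7.37-fold), and Coro1a (6.43-fold, with CAR arrays at 3.90 and 5.16 against 7.22). Of 24 neutrophil and granulocyte genes 18 fell and 0 rose (21 and 0 adjusted over the list alone), with a median of −2.37; Camp and Ly6g led, with Mmp8, neutrophil collagenase, 10.2-fold lower and Ifitm6 8.70-fold lower. Of 25 macrophage and monocyte genes 8 fell and 2 rose (13 and 2 adjusted over the list alone). Tyrobp, Fcgr3 and C1qc were 8.09-fold, 7.89-fold and 7.11-fold lower, Fcgr3 with unequal CAR arrays at 4.13 and 2.73 against 6.41, and Vcam1, which is also a CAR marker, was higher. Of 23 B lymphoid and plasma cell genes 9 fell and 2 rose (10 and 2 adjusted over the list alone), with Rag1 and Cd79b (8.31-fold), a B cell receptor chain, lower, and Sdc1 (7.41-fold) and Ebf1 (6.19-fold), also a CAR marker, higher. Camera gave adjusted p = 6.78e-09, 1.03e-12, 0.000719 and 0.00265 for the 4 lists (adjusted p = 0.600 for each with an estimated correlation). On the CAR arrays 21 of the 24 neutrophil genes lay at or above the median level, which alone does not show expression without detection calls. S100a8, S100a9 and Lyz2, however, had CAR means of 9.86, 10.09 and 8.54, above the 95th percentiles of 6.69 and 6.93 on the CAR arrays, while Ly6g stood at 3.62. Signal of neutrophil genes was therefore not confined to the array labelled PaS.

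Markers of other cell types were compared in the same way. Of 23 endothelial genes 8 fell and 0 rose (11 and 0 adjusted over the list alone), with the endothelial cadherin Cdh5 9.46-fold, Emcn 8.78-fold, Fabp4 7.54-fold and Stab2 3.68-fold lower in CAR cells. Their camera adjusted p was 7.15e-05 (adjusted p = 0.600 with an estimated correlation). Of 20 T and NK cell genes 3 fell (Thy1, Cd2 and Il7r) and 0 rose (likewise 3 and 0 adjusted over the list alone). For these, camera gave adjusted p = 0.00631 (adjusted p = 0.600 with an estimated correlation), and 0.144 after quantile normalization. Their median of −0.63 lay within the middle 95% of matched random lists. It was −0.18 after quantile normalization and −1.58 among genes at or above the median level. The erythroid list (1 of 15 fell, Hemgn) and the megakaryocyte list (2 of 14 fell, Pf4 and Tubb1) each had a camera adjusted p of 0.0512, with 0 and 2 falling adjusted over the list alone; 4 alternatives took the erythroid list and 3 the megakaryocyte list under 0.05, and both medians lay below the middle 95% of matched random lists. The erythroid gene Car1 differed between the CAR arrays, at 3.04 and 7.37 against 8.61, and did not pass (adjusted p = 0.212). Camera made no call for osteoclast (adjusted p = 0.224), smooth muscle and pericyte (0.406), skeletal muscle (0.324) or Schwann and neural genes (0.589). The Schwann and neural median of −0.08, against a mean of 0.27, changed sign with the array and the scaling: it was −0.33 without CAR array 1, 0.19 without CAR array 2, 0.06 after centring and 0.17 after quantile normalization. Of their 12, 20, 20 and 13 measured genes, 0, 3, 0 and 2 rose and 1 fell in each list (1, 3, 0 and 4 rose and 2, 1, 1 and 1 fell adjusted over the list alone). The contractile and pericyte genes Myl9 and Pdgfrb were 31.6-fold and 25.7-fold higher in CAR cells.

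Cell cycle genes were lower in CAR cells, and immediate early genes higher. Of 39 cell cycle genes 20 fell and 0 rose (28 and 0 adjusted over the list alone), with a median of −1.54. The mitotic kinase Aurkb was 6.20-fold, the kinetochore gene Cenpf 6.04-fold, the ribonucleotide reductase subunit Rrm2 5.82-fold and the topoisomerase Top2a 5.65-fold lower. They moved with the blood cell markers, whose general list had a median of −1.90. Of 31 immediate early and stress genes 10 rose and 0 fell (10 and 0 adjusted over the list alone), led by Egr2 (5.67-fold), Ccn2 (5.51-fold), Socs3 (4.96-fold) and Ccn1 (3.63-fold). The camera adjusted p was 7.75e-11 for cell cycle and 4.41e-05 for immediate early genes (adjusted p = 0.600 for each with an estimated correlation). The immediate early call was lost among genes at or above the median level (adjusted p = 0.0659), and its median of 0.76 lay within the middle 95% of matched random lists.

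**Figure D3:**
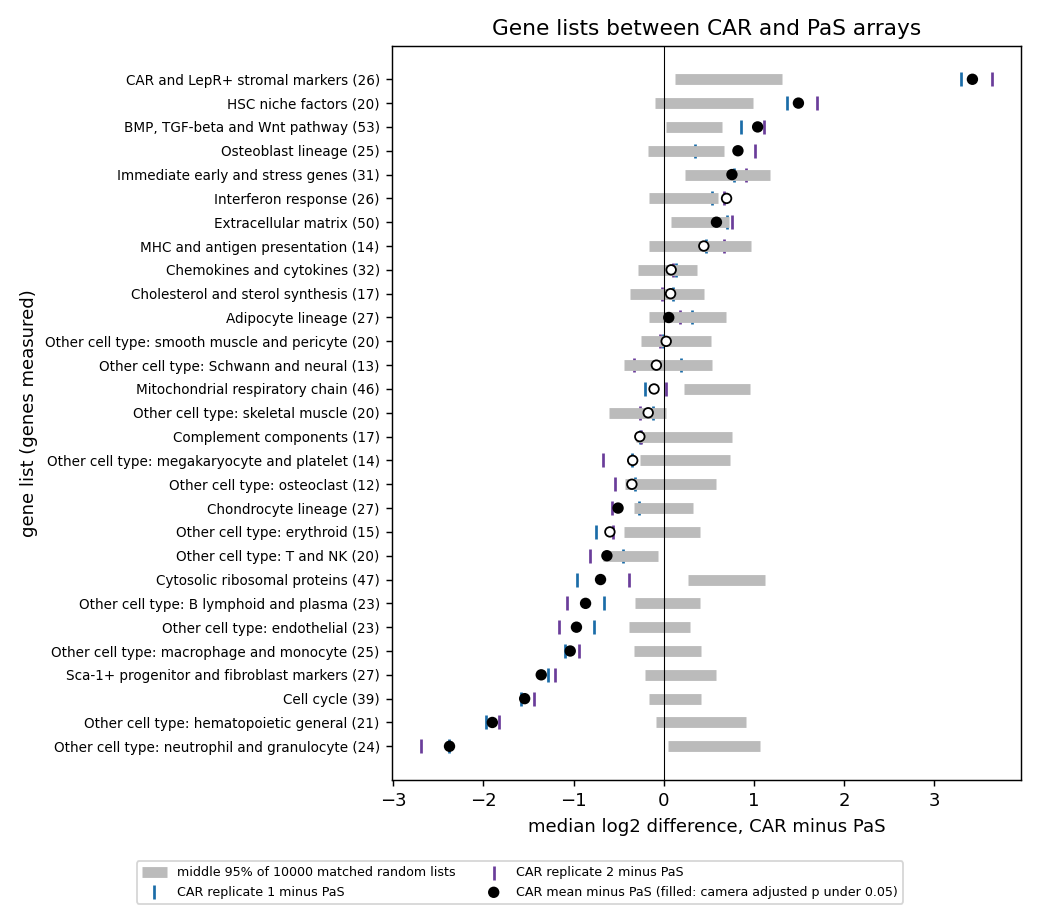
Median log2 difference, CAR minus the array labelled PaS, of the 29 gene lists (number of measured genes in brackets): circles give the CAR mean, filled where camera's adjusted p was under 0.05, ticks give each CAR array alone, and grey bars the middle 95% of 10000 random lists matched on mean expression. CAR markers stand highest at 3.42 and neutrophil genes lowest at −2.37.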

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

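Named genes were followed under centring, quantile normalization, the mean of all probe sets, eBayes with a trend or a robust prior, and with each CAR array left out. The direction of all 127 was kept under these. Apart from the genes of the sorts and the niche, they were named for large differences in these same data, which favours a kept direction. For the 12 largest differences each way, both CAR arrays had to lie on one side, so leaving out 1 could not change the direction. Where a limma test was possible, 1 of the 107 called lost its call (H2-Aa with the mean of all probe sets, adjusted p = 0.0503). The filter on dim genes and the stricter test against 1 log2 unit were not followed for named genes. Of the planned settings, centring moved the median difference of all genes from −0.10 to 0.04 and raised the number of called genes from 2987 to 4725; quantile normalization gave 5357, of which 2819 were among the 2987 with the same sign, an adjusted p under 0.1 gave 5562, and a test against 1 log2 unit gave 228, of which 182 were higher in CAR cells. The number of genes at least 2-fold apart in both CAR arrays, 3956, fell to 2611 among genes at or above the median level, to 2589 when quantile normalization was added (chosen after seeing the data) and to 733 at 2 log2 units. With 1 CAR array left out, it ranged from 4848 (without replicate 2) to 6042 (without replicate 1), more because only 1 array then had to pass. The filter raised the share of calls that were higher in CAR cells from 57.1% to 80.2%, and an intensity trend lowered it to 47.9%. Without the genes of the other cell type and cell cycle lists, also chosen after seeing the data, 2896 genes were called. The mean SD of differences between CAR and PaS arrays moved from 1.02 to 1.12 among genes at or above the median level. Of the 17 lists called, 0 were called with an estimated correlation (also 0 at an unadjusted p under 0.05), where camera has 1 degree of freedom; other alternatives called 16 to 19, and no called list changed direction. Against matched random lists 17 medians lay outside the middle 95%, 5 above and 12 below: the adipocyte, matrix, immediate early and T and NK lists lay within it, and the interferon, erythroid, megakaryocyte and respiratory chain lists outside it. Erythroid and megakaryocyte genes gained a call after centring (adjusted p = 0.0399 each), after quantile normalization (0.0322 and 0.00323) and among genes at or above the median level (0.000306 and 0.00045), and erythroid genes also with camera on ranks (0.0462). The causes of these shifts were not tested. No paired analysis was possible because the CAR and PaS cells came from different mice. Leaving out a CAR array leaves no degrees of freedom and so no test, and without the array labelled PaS no comparison exists.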

Other observations

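Several gene groups fixed before the data were examined fell outside the comparisons above. Complement genes went both ways: of 17 measured, 6 rose in CAR cells and 5 fell (7 and 6 adjusted over the list alone), camera adjusted p = 0.540, a median of −0.27 and a mean of 0.45, with C4b (10.8-fold), Clu (10.4-fold), Serping1 (9.68-fold) and C1s1 (8.59-fold) higher in CAR cells and C1qc, a macrophage product, 7.11-fold lower. Of 26 interferon response genes 4 rose and 3 fell (7 and 5 adjusted over the list alone); Rtp4, Ifit1 and Ifih1 were 8.76-fold, 2.96-fold and 2.95-fold higher, Ifi27l2a was 6.70-fold lower, and camera gave adjusted p = 0.0796, while the median of 0.70 lay above the middle 95% of matched random lists. In the antigen presentation list, 1 of 14 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.183): Tap1, the peptide transporter, was 4.60-fold higher, and the class II genes Cd74, H2-Aa and H2-Ab1 were 4.59-fold, 4.55-fold and 3.08-fold lower. Another class II gene, H2-Eb1, went the other way, 2.22-fold higher in CAR cells, without passing (limma adjusted p = 0.105). Sterol synthesis genes gave 0 calls among 17 (0 adjusted over the list alone, 3 at an unadjusted p under 0.05, camera adjusted p = 0.492).

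Ribosomal protein genes lay lower in CAR cells as a group, with a median of −0.70 over 47 measured genes and camera adjusted p = 7.63e-05 (adjusted p = 0.684 with an estimated correlation); without CAR array 1 the median was −0.39. Of these genes 2 fell and 0 rose (0 and 0 adjusted over the list alone), among them Rps28 (3.29-fold), and their many near-identical copies make single values uncertain. Of 46 respiratory chain genes 5 rose and 1 fell (5 and 4 adjusted over the list alone). Ndufs4, Cox8a and Ndufc1 were 6.03-fold, 3.73-fold and 3.47-fold higher and Cox4i1 5.07-fold lower, with CAR arrays at 5.40 and 6.62 against 8.35. Camera made no call (adjusted p = 0.540), while the median of −0.11, against a mean of 0.04, lay below the middle 95% of matched random lists, 0.22 to 0.96. Its sign was not stable: the median was 0.02 without CAR array 1, −0.21 without CAR array 2, 0.03 after centring and −0.47 after quantile normalization.

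The tests of blood cell RNA and of dilution below were chosen after the result was seen. The first pattern is the blood cell signal on an array whose sort excluded CD45+ and lineage+ cells. The general blood cell list had a median of −1.97 and −1.83 against each CAR array, outside the middle 95% of matched random lists (−0.09 to 0.91), and S100a8, S100a9, Lyz2, Camp and Ptprc were each at least 2-fold higher on the array labelled PaS. The narrower spread of that array is argued against, since quantile normalization left the list's median at −2.31. RNA of blood cells in the PaS sample, in a larger share than in the CAR samples, is a candidate explanation (median −1.90, CAR mean minus PaS, with neutrophil, B cell and macrophage genes together). These values restate the pattern, so they cannot decide whether blood cell RNA is its source. Expression of these genes by the sorted cells themselves was not tested, nor was the source of the cell cycle transcripts that moved with them.

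The second pattern is the low Pdgfra and Prrx1 on the array labelled PaS. The narrower spread is argued against: after quantile normalization Pdgfra was 3.18 ± 0.27 and Prrx1 2.27 ± 0.26 log2 units higher in CAR cells. Dilution by RNA of blood cells cannot be told apart from lower levels in the sorted cells. The same limit applies to the other stromal genes that were higher in CAR cells. The other Sca-1+ genes, 26 without Pdgfra, had a median CAR minus PaS difference of −1.41. As a group they were thus higher on the array labelled PaS, where Pdgfra was lower. Their undiluted level is unknown, however, and several are also made by blood cells. Prg4, Chad, Comp and Clec3a, genes of cartilage or joint tissue, were high on the same array. Other cartilage genes differed less between the arrays. Acan and Cytl1 leaned the same way without passing the test, with CAR minus PaS differences of −1.15 and −0.99 log2 units. For Col2a1, Sox9 and Col9a1 the differences were only −0.19, 0.17 and 0.04. A sample other than the one named in the label was not tested.

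The third pattern concerns dim genes. The 1194 olfactory and vomeronasal receptor genes, a group chosen after the data were seen, had a median difference of −0.70, and 214 of them were called lower in CAR cells (16.7% of all lower calls) against 1 called higher. Their median levels were 2.17 and 1.91 on the CAR arrays and 2.83 on the array labelled PaS, below the median of all genes. A narrower spread on the PaS array is a candidate explanation: quantile normalization brought the median to −0.21, between the bounds set in advance, so it remains open as the whole cause. After it 224 were called lower, 182 of them among the 214, and 27 higher; the 224 made up 8.84% of all lower calls.

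A search over 232 gene families defined by a shared symbol stem, chosen after the data were seen, gave 27 past an adjusted p of 0.05 in camera, 11 higher and 16 lower in CAR cells; the smallest adjusted p with an estimated correlation was 0.883. After quantile normalization 3 kept their call and direction: Rpl (ribosomal proteins) and Ceacam (adhesion molecules of epithelia and granulocytes) lower, and Zcchc (zinc finger proteins) higher. Families such as Tas (taste receptors), Prl (prolactin relatives) and Defb (beta-defensins), with medians of −0.58, −0.83 and −0.54 as deposited, had −0.12, −0.32 and −0.23 after it.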
